A study of Homo sapiens with 9 samples.

How the data were processed

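RNA-seq of human primary melanocytes (NHEM-c, passage 12) was analysed in 9 libraries of 3 groups, with 3 libraries each: no exosomes, A375 exosomes and A549 exosomes. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, exosomes were prepared by differential centrifugation and ultracentrifugation from medium with exosome-depleted serum, and 250 µl at an optical density of 0.05 at 420 nm was added at each of 2 times on the same day. RNA was isolated 16 h later with a total RNA kit, and libraries were made with a stranded poly-A kit, per the labels' protocols. The labels describe the control as cells without exosomes and describe no vehicle arm.

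The deposited table holds FPKM (fragments scaled by gene length and by mapped fragments) that the authors made with Cuffnorm, per the submitters' processing notes. Those notes also name FastQC 0.10.1, TopHat2 2.0.13 and the build hg38. The Cuffnorm version, its scaling method and the annotation are not given in the sources used here. Cuffnorm scales libraries to each other, so a shift common to all genes of a group cannot be seen in these values. FPKM holds no counts, so no count model was used, and depth was read only as relative depth from whole steps of rows under 0.3 FPKM (tolerance 0.01 on the log2 scale). Between 37.4% and 41.8% of the low rows compared lay on such steps, so whole fragments were not recovered for all genes. All 13 mitochondrially encoded protein genes were listed at 0 in every library, so an exact 0 in this table was read only as listed at 0.

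Gene symbols and GRCh38 coordinates came from the GENCODE 29 annotation and a gene name table, matched by gene identifier. Of 60603 rows, 41160 had a symbol and 56922 had coordinates, and 64 symbols stood on more than 1 row and were not named. Near-identical gene copies and pseudogenes can share fragments, and the authors' counting of those is not given in the sources used here.

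Rows with at least 1 FPKM in at least 3 libraries were kept (16029 rows), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (a linear model on group with a trended empirical Bayes variance). All 9 libraries entered 1 fit with 3 contrasts, which share 1 estimate of the spread. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all rows tested, and genes with adjusted p under 0.05 were called. Every adjusted p of a gene comes from limma. Counts of genes changed at least 2-fold use the same test with an absolute log2 change of at least 1.

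Gene lists of pathways and cell type markers (37 in all) were fixed before the data were examined, as were the design, the rule for named genes and 19 of the settings tried, and 4 settings were added afterwards. The 33 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. The named genes were the 10 largest rises and 10 largest falls per contrast among genes that passed, whose groups did not overlap and whose higher group mean was at least 2 FPKM. Up to 4 members per list with the largest changes were added (2 where none passed), with a fixed set of melanocyte and transition genes. Genes without a symbol, small RNA genes and sex-linked genes used to tell sexes apart were never named. Results for some single genes that the rule names are not reported here. A gene named in 1 contrast is also given in the others where that shows how the groups stand, and KRT17, DCN and CXCL12, as markers above 3 FPKM, were chosen after their values were seen.

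The simulation of unchanged groups against the shared controls used 100 draws. Settings tried were another pseudocount (0.1), no filter, a filter at 5 FPKM, TPM rescaling, median-of-ratios scaling, quantile normalization, only the 2 groups compared, robust variances, a replicate block, leaving out each library and, for lists, camera with an estimated correlation. The added ones were TPM rescaling without 8 rows, A549 replicate 1 alone, protein-coding genes only and removal of the trend on GC content (loess span 0.5). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the plots.

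The fit was tested on simulated data for the comparison of A375 exosomes with control, over 16029 rows of which 200 were changed. It recovered 24 of 67 rows with a log2 change of 0.5 (35.8%), 60 of 67 with a change of 1 (89.6%) and 61 of 66 with a change of 2 (92.4%), and called 8 unchanged rows. Among 33 lists, the 1 shifted by 0.5 was called and 0 others were. Each gene was simulated on its own, so this does not test list calls where members move together between libraries.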

Results

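The data were poly-A RNA-seq libraries of human primary melanocytes (NHEM-c), the pigment cells of the epidermis, grown in melanocyte medium. Cultures received exosomes from A375, an established human melanoma line, from A549, an established human lung adenocarcinoma line, or no exosomes. Exosomes are small membrane vesicles that cells release, and here they were pelleted from the medium of each line. Each of the 3 groups held 3 libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The comparisons ask which genes of normal melanocytes differ after contact with vesicles of a melanoma line, and whether vesicles of a carcinoma line of another tissue do the same. The table listed FPKM for 60603 rows, of which 41160 (67.9%) carried a gene symbol and 16029 were tested. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

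Total counts were not used here, since the table holds FPKM. The value of 1 fragment, read from whole steps among low values, gave depths relative to control replicate 1 of 0.957 ± 0.080 in control (SD, n = 3), 0.791 ± 0.064 in the A375 group and 0.716 ± 0.192 in the A549 group. A549 replicates 2 and 3 were the shallowest, at 0.593 and 0.618. Between 14909 and 15581 rows reached 1 FPKM per library. Spearman correlations across rows were 0.957 to 0.974 within groups and 0.926 to 0.942 between the A549 libraries and the others. The first principal component, 41.4% of the variance, placed the A549 libraries at 47.8 to 50.6 and the other 6 at -32.2 to -13.9. Column sums lay between 739253 and 777482 FPKM except in A549 replicate 2, at 990048. In that library 8 rows on chromosome 1 held 25.4% of the sum and were listed at 0 elsewhere. Of these, 7 are named as mitochondrial pseudogenes, while 1 row of a miRNA gene without a symbol alone held 19.9% of the sum.

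After A375 exosomes, melanocytes carried more mRNA of the SMAD target genes ID3 and TGFBI and less mRNA of the cytokine gene IL24 and of the cholesterol pathway. ID3, an inhibitor of basic helix-loop-helix transcription factors, rose from 1.32 ± 0.0752 to 45.5 ± 18.7 FPKM (SD, n = 3 per group), a log2 change of 4.25 ± 0.24, adjusted p = 0.00016 by limma. TGFBI, a matrix protein induced by TGF-beta, rose from 64.3 ± 4.52 to 192 ± 5.36 FPKM (1.57 ± 0.06, adjusted p = 4.9e-05). IL24, a cytokine made by melanocytes, fell from 153 ± 25.6 to 31.0 ± 3.26 FPKM (-2.26 ± 0.13, adjusted p = 0.00016). HMGCS1, which makes HMG-CoA for sterol synthesis, fell from 178 ± 13.4 to 78.3 ± 7.93 FPKM (-1.17 ± 0.08, adjusted p = 0.00061). In GRCh38 with GENCODE 29, ID3 (ENSG00000117318) lies on chromosome 1, 23557918 to 23559794, minus strand, TGFBI (ENSG00000120708) on chromosome 5, 136028895 to 136063818, plus strand, IL24 (ENSG00000162892) on chromosome 1, 206897443 to 206904139, plus strand and HMGCS1 (ENSG00000112972) on chromosome 5, 43289395 to 43313512, minus strand.

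**Figure D1:**
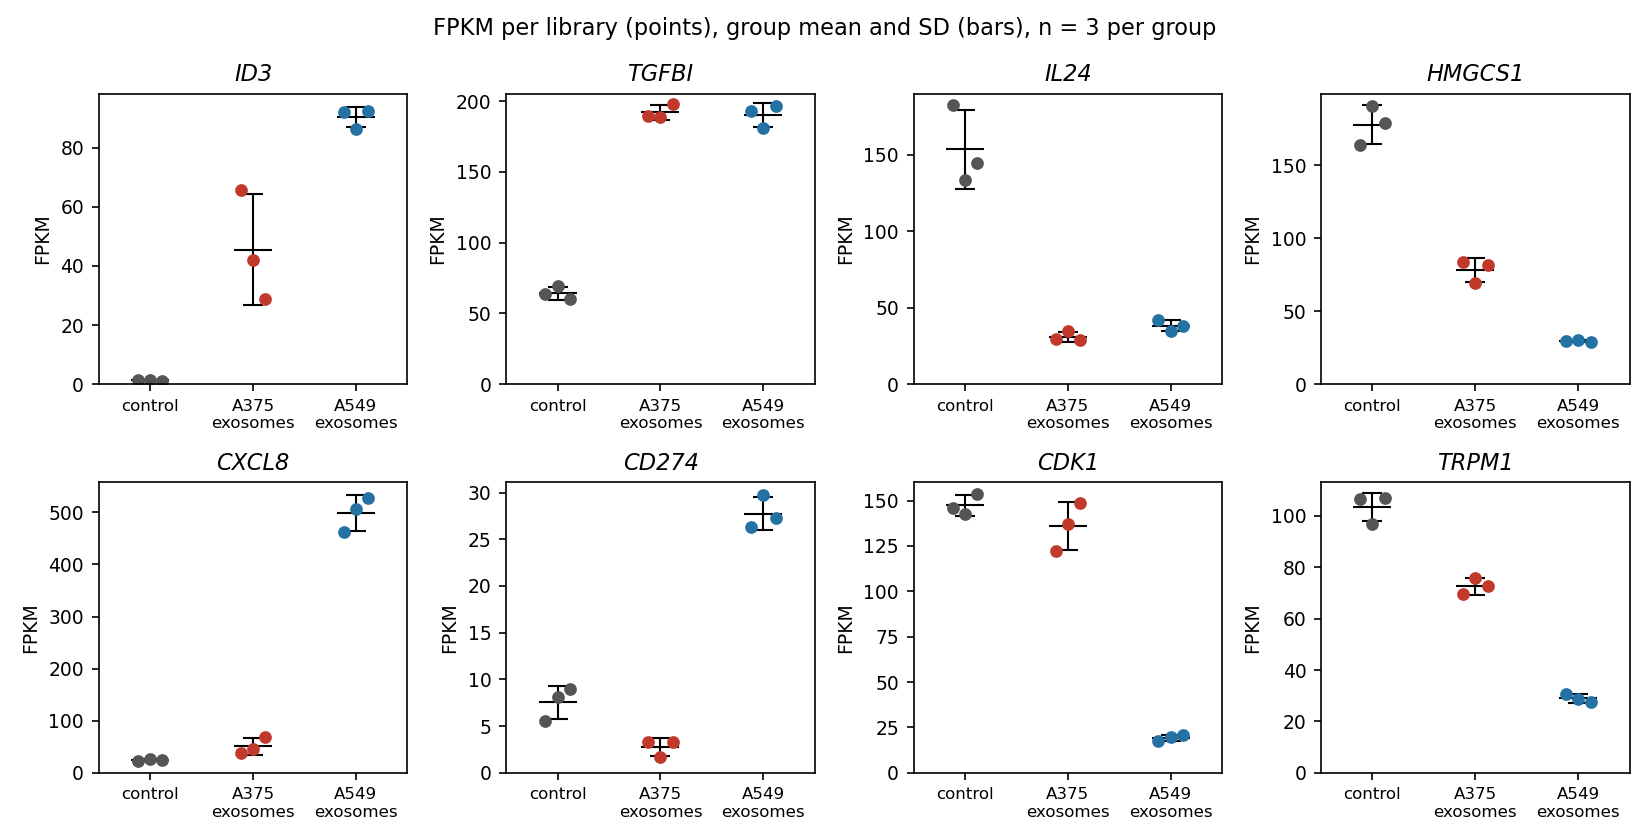
FPKM (y axis, from 0) of 8 genes in each library (points), with the group mean and SD as bars, in control, A375 exosome and A549 exosome groups of 3 libraries each. TGFBI was at 64.3 FPKM in control against 192 and 190.2 in the A375 and A549 groups, while CDK1 was at 147, 136 and 19.2 FPKM.

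In the comparison of A375 exosomes with control, 395 genes changed at adjusted p under 0.05, 202 higher and 193 lower, and 51 of them changed at least 2-fold, 32 higher and 19 lower. Rescaling each library to the same sum (TPM) left 52 genes, 32 higher and 20 lower, and quantile normalization gave 231 higher and 143 lower. Without the 8 rows of A549 replicate 2, TPM rescaling gave 201 higher and 156 lower. Fitting only these 2 groups gave 110 genes, and removing a trend on GC content gave 871. The count was 142, 134 and 165 without control replicates 1, 2 and 3, 133 without A375 replicate 2, and 235, 241 and 234 without A549 replicates 1, 2 and 3. At least 2-fold changes numbered 27 without control replicate 1 and 33 without control replicate 3. Without control replicate 3 the split was 101 higher and 64 lower, and without A375 replicate 1 it was 226 higher and 291 lower.

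Of 23 tested TGF-beta targets, 7 rose, 0 fell and 16 did not pass, or 12 up and 0 down adjusted over the list alone (camera median 0.23, adjusted p = 2.8e-09; adjusted p = 0.093 with an estimated correlation). PMEPA1, a feedback inhibitor of TGF-beta signalling, rose from 2.74 ± 0.411 to 12.1 ± 0.649 FPKM (log2 1.82 ± 0.10, adjusted p = 0.00015). ID2, a relative of ID3, rose from 21.7 ± 1.69 to 103 ± 18.7 FPKM (log2 2.19 ± 0.12, adjusted p = 0.00015). Of 22 basement membrane and matrix genes 5 rose and 1 fell, or 8 up and 2 down adjusted over the list alone (adjusted p = 0.00013; adjusted p = 0.086 with an estimated correlation). Among them FN1, the gene of fibronectin, rose from 311 ± 21.3 to 458 ± 29 FPKM, TNC, the gene of tenascin C, from 57.6 ± 4.86 to 84.9 ± 4.29, and NID1, the gene of the basement membrane protein nidogen 1, from 33.9 ± 1.14 to 45.8 ± 0.494. Their log2 changes were 0.56 ± 0.06, adjusted p = 0.0048 for FN1, 0.56 ± 0.07, adjusted p = 0.0073 for TNC and 0.42 ± 0.05, adjusted p = 0.0039 for NID1.

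Of 25 NF-kB and inflammatory cytokine genes, 11 rose, 1 fell and 13 did not pass, or 12 up and 2 down adjusted over the list alone (camera median 0.32, adjusted p = 1.6e-10; adjusted p = 0.083 with an estimated correlation). CXCL5, a neutrophil chemoattractant, rose from 23.3 ± 3.96 to 94.3 ± 25.1 FPKM (log2 1.95 ± 0.18, adjusted p = 0.0023), and the related CXCL3 from 2.16 ± 0.521 to 8.04 ± 1.87 FPKM (log2 1.51 ± 0.17, adjusted p = 0.0039). Interferon response genes had a camera median of -0.73 (adjusted p = 7.9e-12; adjusted p = 0.32 with an estimated correlation), with all 35 tested members below 0. By limma 0 of them passed, over all genes or adjusted over the list alone, and 21 had an unadjusted p under 0.05. The antiviral gene OAS3 was at 157, 209 and 169 FPKM in the 3 control libraries and at 145, 69.4 and 105 in the 3 A375 libraries. Without A375 replicate 2 the median of the interferon list was -0.37, with 0 called by limma. Without A375 replicate 1 it was -0.90, with 6 called lower. MHC class I and antigen processing genes had a median of -0.20 (adjusted p = 0.025; adjusted p = 0.57 with an estimated correlation), with 0 of 17 passing by limma, or 0 up and 0 down adjusted over the list alone, and 4 at unadjusted p under 0.05. That list was not called without control replicate 2 (adjusted p = 0.31), A375 replicate 2 (0.14) or A375 replicate 3 (0.13), or with the trend on GC content removed (0.064). Its median was -0.31 without A375 replicate 1, -0.12 without control replicate 2 and -0.12 without A375 replicate 3.

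Cholesterol synthesis and uptake genes fell together: 21 of 24 tested fell and none rose, or 0 up and 23 down adjusted over the list alone (camera median -0.64, adjusted p = 1.2e-32; adjusted p = 0.027 with an estimated correlation). The number that fell was 14, 12 and 14 without control replicates 1, 2 and 3, 12 without A375 replicate 2, 12 with only the 2 groups compared, 14 with no filter and 5 under TPM rescaling. TPM rescaling without the 8 rows of A549 replicate 2 gave 20. FDPS, which makes farnesyl diphosphate, fell from 377 ± 3.29 to 205 ± 16.2 FPKM (log2 -0.88 ± 0.07, adjusted p = 0.00087). INSIG1, a sterol-regulated brake on SREBP processing, fell from 133 ± 7.66 to 69.5 ± 6.08 FPKM (log2 -0.93 ± 0.09, adjusted p = 0.0023). Of 14 fatty acid synthesis and desaturation genes 5 fell and 0 rose, or 0 up and 8 down adjusted over the list alone (median -0.44, adjusted p = 2.0e-09; adjusted p = 0.027 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate, fell from 114 ± 13.1 to 46.3 ± 5.42 FPKM (log2 -1.28 ± 0.11, adjusted p = 0.0017), and the stearoyl-CoA desaturase SCD from 988 ± 53.3 to 706 ± 33.6 FPKM (log2 -0.48 ± 0.06, adjusted p = 0.0055). Of 9 LXR targets and cholesterol efflux genes 1 fell and 0 rose, or 0 up and 1 down adjusted over the list alone, and the list was not called (adjusted p = 0.11). The efflux transporter ABCA1 had a log2 change of 0.02 ± 0.09, adjusted p = 0.95.

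**Figure D2:**
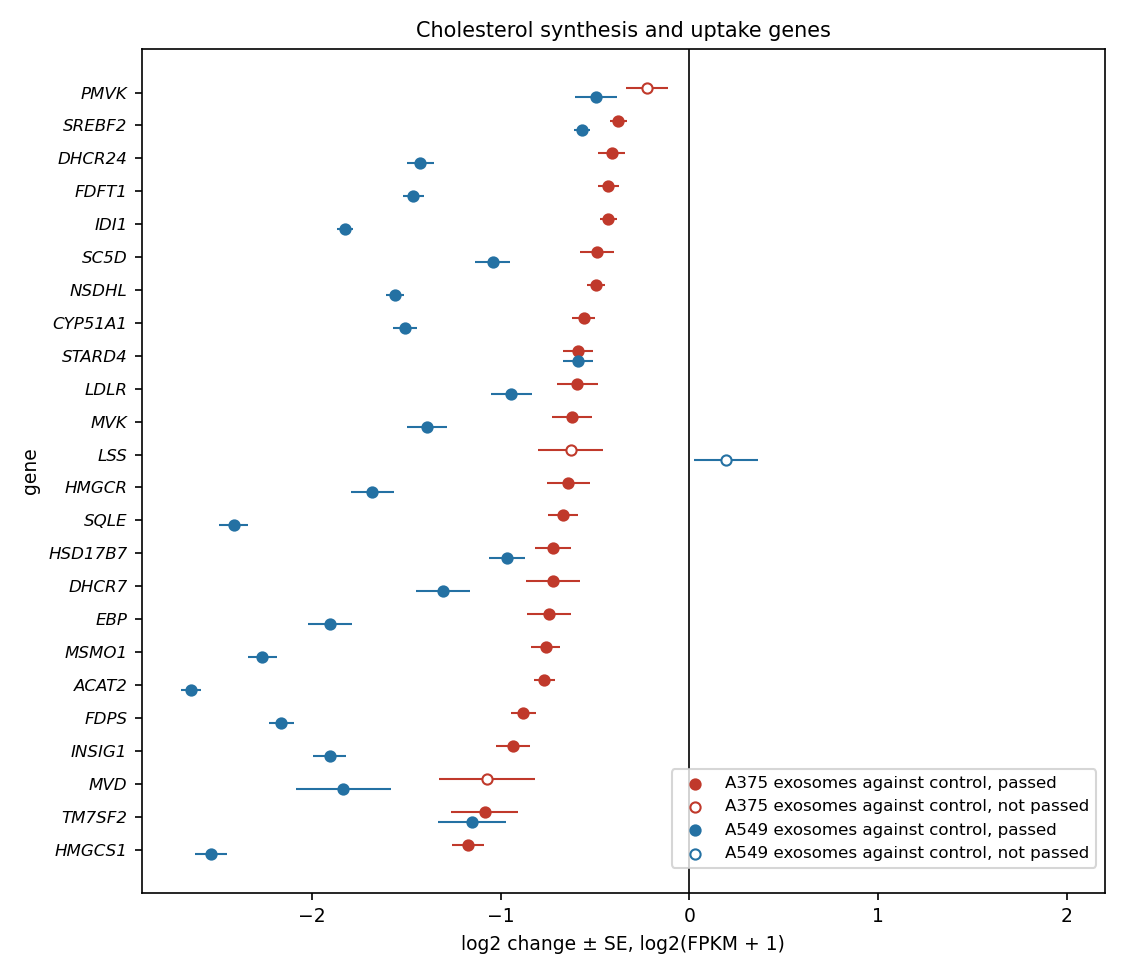
Log2 change ± SE on log2(FPKM + 1) (x axis) of the 24 tested cholesterol synthesis and uptake genes (y axis) after A375 and after A549 exosomes, each against control, n = 3 per group; filled points passed adjusted p under 0.05. After A375 exosomes 21 fell (12 to 21 without 1 library, 5 under TPM rescaling and 20 under TPM rescaling without the 8 rows of A549 replicate 2). After A549 exosomes 23 fell (23 in each of these fits).

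Pigmentation genes were not called as a list after A375 exosomes (median 0.00, adjusted p = 0.46), with 1 risen and 3 fallen of 24, or 1 up and 5 down adjusted over the list alone. TRPM1, a melanocyte ion channel controlled by MITF, fell from 104 ± 5.61 to 72.6 ± 3.21 FPKM (log2 -0.51 ± 0.06, adjusted p = 0.0069). MITF, the master regulator of the lineage, was at 159 ± 8.06 and 143 ± 8.79 FPKM (log2 -0.16 ± 0.06, adjusted p = 0.26). The 15 melanocyte lineage and neural crest genes held 2 risen and 0 fallen, or 6 up and 1 down adjusted over the list alone (median 0.13, adjusted p = 0.0017; adjusted p = 0.083 with an estimated correlation). CDH19, a cadherin of Schwann cell precursors, rose from 22.4 ± 0.241 to 37.0 ± 3.63 FPKM (log2 0.70 ± 0.07, adjusted p = 0.0028).

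Of 29 mesenchymal genes, which mark epithelial-mesenchymal transition, 5 rose and 2 fell, or 11 up and 3 down adjusted over the list alone (median 0.08, adjusted p = 0.00084; adjusted p = 0.086 with an estimated correlation). Of 13 epithelial genes 1 fell, or 0 up and 3 down adjusted over the list alone (median -0.27, adjusted p = 0.0075; adjusted p = 0.14 with an estimated correlation), and the list was not called with a filter at 5 FPKM (adjusted p = 0.099). CDH1, the gene of E-cadherin, was at 71.6 ± 3.44 and 52.9 ± 10.1 FPKM (log2 -0.45 ± 0.16, adjusted p = 0.25), and VIM, the gene of vimentin, at 1751 ± 42.2 and 1828 ± 50.9 (log2 0.06 ± 0.04, adjusted p = 0.53). ZEB1 and TWIST1, transcription factors of that transition, were below the filter, at 0.158 and 0.0347 FPKM in control and 0.209 and 0.113 in the A375 group. Of 24 targets of let-7, a microRNA family, limma called 0, over all genes or adjusted over the list alone, with 2 at unadjusted p under 0.05, and the list was not called (adjusted p = 0.48). Its members LIN28B and HMGA2 were below the filter, at 0.00556 and 0.219 FPKM in control and 0.0177 and 0.396 in the A375 group. Of 22 genes of ERK pathway output 3 rose and 0 fell, or 5 up and 0 down adjusted over the list alone, with no call for the list (adjusted p = 0.48). The number that rose was 0 to 4 in the fits without 1 library. It was 0 under TPM rescaling and 0 with only the 2 groups compared, with 3 and 7 members at unadjusted p under 0.05.

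Of 45 cell cycle genes 8 fell and 0 rose, or 0 up and 13 down adjusted over the list alone (median -0.16, adjusted p = 2.4e-08; adjusted p = 0.093 with an estimated correlation). CDK1, the mitotic kinase, had a log2 change of -0.12 ± 0.08, adjusted p = 0.58. Of 25 p53 targets 2 fell and 0 rose, or 0 up and 7 down adjusted over the list alone (camera median -0.27, adjusted p = 8.1e-06, and adjusted p = 0.093 with an estimated correlation). The number that fell was 0 to 5 in the fits without 1 library. It was 0 under TPM rescaling and 0 with only the 2 groups compared, with 3 and 10 members at unadjusted p under 0.05. Of 28 apoptosis regulators 2 rose and 0 fell, or 3 up and 1 down adjusted over the list alone, with no call for the list (adjusted p = 0.70). The pro-apoptotic gene BCL2L11 rose from 6.16 ± 0.182 to 9.64 ± 0.793 FPKM (log2 0.57 ± 0.07, adjusted p = 0.0069). The anti-apoptotic gene BCL2A1 rose from 60.2 ± 5.18 to 83.5 ± 9.51 FPKM (log2 0.46 ± 0.09, adjusted p = 0.043), a call lost in 8 of the 9 fits without 1 library (adjusted p = 0.075 to 0.17) and kept without A375 replicate 1. MYOF, a membrane repair gene, fell from 47.3 ± 2.38 to 28.8 ± 1.57 FPKM (log2 -0.70 ± 0.06, adjusted p = 0.0015). PADI1, a peptidylarginine deiminase, and the noncoding LINC01291 fell by 1.05 ± 0.11 and 1.22 ± 0.13 on the log2 scale. The YAP/TAZ target list was lower (1 rose and 5 fell of 20, or 2 up and 8 down adjusted over the list alone, adjusted p = 0.019; adjusted p = 0.17 with an estimated correlation) and was not called without A375 replicate 3 (adjusted p = 0.071). The heat shock list was lower (1 fell of 21, or 0 up and 3 down adjusted over the list alone, adjusted p = 0.013; adjusted p = 0.20 with an estimated correlation) and was not called without control replicate 3 (0.081) or A375 replicate 1 (0.12). The NRF2 list was higher (adjusted p = 0.0052; adjusted p = 0.093 with an estimated correlation), with 0 of 25 members passing by limma, or 2 up and 1 down adjusted over the list alone, and 6 at unadjusted p under 0.05. The integrin list was higher (1 rose and 1 fell of 14, or 3 up and 2 down adjusted over the list alone, adjusted p = 0.040; adjusted p = 0.13 with an estimated correlation). That call was lost in 11 of the 22 settings. It was lost without control replicate 1 (0.052), 2 (0.054) or 3 (0.056) and A375 replicate 1 (0.066) or 3 (0.089). It was also lost with no filter (0.091), a filter at 5 FPKM (0.077), TPM rescaling with (0.086) or without (0.069) the 8 rows, and quantile normalization (0.059).

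Camera called 17 of the 33 tested lists after A375 exosomes, 8 higher and 9 lower, of which the cholesterol and fatty acid lists were also called with an estimated correlation. Without 1 library the median of the lineage list was 0.06, 0.20 and 0.21 (A375 replicates 1, 2 and 3). That of the p53 targets was -0.14 (A375 replicate 3). That of the epithelial list was -0.16 and -0.17 (A375 replicates 1 and 2), and that of the mesenchymal list 0.05 (control replicate 2). It was 0.22 for the lineage list with the trend on GC content removed and 0.16 for the mesenchymal list with a filter at 5 FPKM. It was -0.02 for the epithelial list with no filter and 0.49 for the NF-kB list at a pseudocount of 0.1. The NF-kB genes that rose numbered 5, 7 and 5 without control replicates 1, 2 and 3, 5 without A375 replicate 2 and 5 under TPM rescaling. The cell cycle genes that fell numbered 1, 1 and 2 without control replicates 1, 2 and 3, 3 without A375 replicate 3 and 5, 5 and 4 without A549 replicates 1, 2 and 3. Limma called 0 of them without A375 replicate 2 and 0 under TPM rescaling, with 16 and 11 at unadjusted p under 0.05. With only the 2 groups compared 1 of them fell. The fatty acid genes that fell numbered 3, 2 and 3 without control replicates 1, 2 and 3 and 9 and 2 without A375 replicates 1 and 2. They numbered 1 under TPM rescaling and 2 with only the 2 groups compared. Without 1 library there were also 1 to 4 fallen YAP/TAZ targets, 3 to 4 risen matrix genes and 3 to 6 risen mesenchymal genes. These 3 counts were 0, 0 and 1 under TPM rescaling and 1, 2 and 3 with only the 2 groups compared. Of the 66 genes named by rule that changed, 16 kept their call under all settings, 47 lost it under TPM rescaling, 40 with only the 2 groups compared, 14 with the replicate block and 40 in at least 1 of the fits without 1 library.

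After A549 exosomes the melanocytes carried more mRNA of chemokines and of complement C3 and less mRNA of cell cycle genes. FDCSP, a small secreted protein that inflammatory cytokines induce, rose from 1.37 ± 0.381 to 241 ± 3.30 FPKM (SD, n = 3 per group), a log2 change of 6.69 ± 0.22, adjusted p = 3.2e-07 by limma. CXCL8, the neutrophil chemokine interleukin 8, rose from 24.1 ± 2.07 to 499 ± 34.0 FPKM (4.32 ± 0.19, adjusted p = 1.2e-06), and C3, the central complement component, from 3.27 ± 0.356 to 224 ± 12.9 FPKM (5.72 ± 0.30, adjusted p = 3.0e-06). CDK1 fell from 147 ± 5.57 to 19.2 ± 1.56 FPKM (-2.88 ± 0.08, adjusted p = 2.5e-07). In GRCh38, FDCSP (ENSG00000181617) lies on chromosome 4, 70226071 to 70235252, plus strand, CXCL8 (ENSG00000169429) on chromosome 4, 73740506 to 73743716, plus strand, C3 (ENSG00000125730) on chromosome 19, 6677704 to 6730562, minus strand and CDK1 (ENSG00000170312) on chromosome 10, 60778331 to 60794852, plus strand.

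A549 exosomes changed 6425 genes against control, 2902 higher and 3523 lower, and 1060 at least 2-fold, 495 higher and 565 lower. The 6425 are 40.1% of all tested genes, so a list with about that share of members called in either direction does not stand out by its count. A count in 1 direction compares with 2902 higher or 3523 lower of 16029 tested genes. TPM rescaling gave 4062 changed genes, 1502 higher and 2560 lower. Without the 8 rows of A549 replicate 2, TPM rescaling gave 3636 higher and 2933 lower. Camera called 18 lists, 11 higher and 7 lower, and 3 with an estimated correlation.

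Of 25 NF-kB and inflammatory cytokine genes 24 rose and 1 fell, or 24 up and 1 down adjusted over the list alone (median 2.32, adjusted p = 1.2e-18; adjusted p = 0.036 with an estimated correlation). CCL20, a lymphocyte chemokine, rose from 0.294 ± 0.0881 to 43.9 ± 1.28 FPKM (log2 5.12 ± 0.10, adjusted p = 1.1e-07), and CXCL2 rose by 5.10 ± 0.25 on the log2 scale. Outside the list UBD, a ubiquitin-like protein induced by interferon gamma and TNF, rose from 4.08 ± 1.70 to 243 ± 9.60 FPKM (log2 5.64 ± 0.23, adjusted p = 8.3e-07). TNFAIP2, a TNF-induced gene, rose by 5.23 ± 0.19 on the log2 scale. Of 17 MHC class I and antigen processing genes 16 rose, or 16 up and 0 down adjusted over the list alone (median 0.82, adjusted p = 2.9e-07; adjusted p = 0.21 with an estimated correlation), among them HLA-B, whose fragments can be shared with related HLA genes, from 2486 ± 237 to 5232 ± 83.2 FPKM and the peptide transporter TAP1 by 1.16 ± 0.18. Of 35 interferon response genes 11 rose and 24 did not pass, or 11 up and 0 down adjusted over the list alone (median 0.48, adjusted p = 0.0011; adjusted p = 0.62 with an estimated correlation). The number that rose was 6 and 7 without control replicates 1 and 3, 7, 7 and 6 without A549 replicates 1, 2 and 3, 16 without A375 replicate 2 and 19 with only the 2 groups compared. OASL, an antiviral protein, rose by 1.42 ± 0.33 and BST2, the gene of tetherin, by 1.42 ± 0.32.

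All 45 tested cell cycle genes fell, over all genes and adjusted over the list alone (median -2.30, adjusted p = 6.1e-32; adjusted p = 0.030 with an estimated correlation). Outside the list the kinetochore gene SPC25 fell from 38.3 ± 0.855 to 3.12 ± 0.698 FPKM. In the list RRM2, the small subunit of ribonucleotide reductase, fell from 98.9 ± 1.39 to 11.8 ± 1.60 FPKM. The log2 changes were -2.97 ± 0.09, adjusted p = 2.5e-07 for RRM2 and -3.27 ± 0.12, adjusted p = 6.0e-07 for SPC25. Of 18 replication-dependent histone genes in the list, 7 passed the filter on FPKM and all 7 rose, or 7 up and 0 down adjusted over the list alone (median 1.17, or 0.49 with no filter, adjusted p = 7.2e-05; adjusted p = 0.12 with an estimated correlation), and H2BC5 and H2BC21, for which polyadenylated transcripts are known, rose by 1.57 ± 0.14 and 1.17 ± 0.09. Of 72 cytosolic ribosomal protein genes 39 fell and 0 rose, or 0 up and 41 down adjusted over the list alone (median -0.23, adjusted p = 3.1e-07; adjusted p = 0.29 with an estimated correlation). Under quantile normalization that median was -0.15. Of 25 p53 targets 4 rose and 8 fell, or 4 up and 8 down adjusted over the list alone, with no call for the list (adjusted p = 0.51).

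Cholesterol synthesis and uptake genes also fell after A549 exosomes, 23 of 24 tested, or 0 up and 23 down adjusted over the list alone (median -1.48, adjusted p = 3.6e-16; adjusted p = 0.080 with an estimated correlation). ACAT2, an acetyl-CoA thiolase, fell from 166 ± 8.46 to 25.7 ± 1.01 FPKM (log2 -2.64 ± 0.05, adjusted p = 1.1e-07), the squalene epoxidase SQLE from 106 ± 5.98 to 19.2 ± 1.15 FPKM (log2 -2.41 ± 0.08, adjusted p = 3.0e-07), and HMGCS1 to 29.7 ± 0.825 FPKM. Of 14 fatty acid genes 12 fell and 0 rose, or 1 up and 13 down adjusted over the list alone (adjusted p = 2.4e-07; adjusted p = 0.036 with an estimated correlation). ABCA1 rose from 2.67 ± 0.147 to 14.5 ± 0.684 FPKM (log2 2.08 ± 0.09, adjusted p = 8.3e-07), while the LXR target and efflux list was not called (adjusted p = 0.88).

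Of 23 TGF-beta targets 16 rose and 2 fell, or 16 up and 3 down adjusted over the list alone (median 0.69, adjusted p = 2.4e-07; adjusted p = 0.12 with an estimated correlation). ID3 rose to 90.3 ± 3.43 FPKM (log2 5.30 ± 0.24, adjusted p = 1.4e-06) and TGFBI to 190.2 ± 8.34 FPKM (log2 1.55 ± 0.06, adjusted p = 6.5e-07). Of 22 matrix genes 13 rose and 1 fell, or 16 up and 1 down adjusted over the list alone (adjusted p = 4.6e-05; adjusted p = 0.085 with an estimated correlation), with FN1 at 828 ± 27.6 FPKM. Of 29 mesenchymal genes 13 rose and 7 fell, or 13 up and 7 down adjusted over the list alone (adjusted p = 0.0094; adjusted p = 0.12 with an estimated correlation), and 4 fell without control replicate 2, A375 replicate 2 or any 1 A549 library. CDH2, the gene of N-cadherin, rose from 8.43 ± 1.01 to 18.5 ± 0.571 FPKM (log2 1.05 ± 0.08, adjusted p = 3.3e-05), CDH1 fell from 71.6 ± 3.44 to 41.6 ± 7.75 (log2 -0.79 ± 0.16, adjusted p = 0.0059), and VIM fell by 0.33 ± 0.04 on the log2 scale. ZEB1 and TWIST1 stayed below the filter, at 0.35 and 0.122 FPKM.

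Of 24 pigmentation genes 18 fell and 0 rose, or 0 up and 18 down adjusted over the list alone (median -0.45, adjusted p = 1.9e-07; adjusted p = 0.12 with an estimated correlation). TRPM1 fell to 28.9 ± 1.68 FPKM (log2 -1.80 ± 0.06, adjusted p = 4.5e-07), MITF to 96.7 ± 3.08 FPKM (log2 -0.71 ± 0.06, adjusted p = 4.2e-05), and SLC45A2, a melanosomal transporter, from 70.3 ± 5.43 to 20.4 ± 2.61 FPKM (log2 -1.74 ± 0.09, adjusted p = 3.4e-06). Of 15 lineage and neural crest genes 8 rose and 2 fell, or 8 up and 2 down adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.12 with an estimated correlation), with CDH19 at 82.2 ± 2.64 FPKM. SOX10, a neural crest transcription factor, had a log2 change of 0.28 ± 0.09, adjusted p = 0.043. That call was lost without control replicate 2 (adjusted p = 0.099), control replicate 3 (0.13), A375 replicate 2 (0.062) and A549 replicates 1 (0.11), 2 (0.13) and 3 (0.055). Metallothionein genes, near-identical copies that can share fragments, rose in 5 of 8 cases, or 6 up and 0 down adjusted over the list alone (adjusted p = 0.0053; adjusted p = 0.29 with an estimated correlation), and MT2A rose by 1.31 ± 0.22. The unfolded protein and integrated stress response list was higher, with 16 risen and 4 fallen of 35, or 16 up and 5 down adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.22 with an estimated correlation).

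The lysosome list was also higher (adjusted p = 0.016; adjusted p = 0.36 with an estimated correlation) and was not called under TPM rescaling (0.077), and the nuclear-encoded respiratory chain list was lower (adjusted p = 0.0047; adjusted p = 0.22 with an estimated correlation) and was not called under quantile normalization (0.15). The heat shock list was lower, with 3 risen and 12 fallen of 21, or 3 up and 13 down adjusted over the list alone (adjusted p = 0.047; adjusted p = 0.29 with an estimated correlation), and 9 of the 22 settings kept that call. The call was lost without control replicate 3 (0.058), A375 replicates 2 (0.051) and 3 (0.054) and A549 replicates 2 (0.070) and 3 (0.054). Under the 7 other settings that ended it, apart from the estimated correlation, the adjusted p was 0.053 to 0.15. Under TPM rescaling 9 MHC class I, 6 interferon response, 8 mesenchymal and 7 unfolded protein response genes rose and 19 ribosomal protein genes fell. Of the 143 named genes that changed after A549 exosomes, 131 kept their call under all settings and 7 lost it in at least 1 fit without 1 library.

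**Figure D3:**
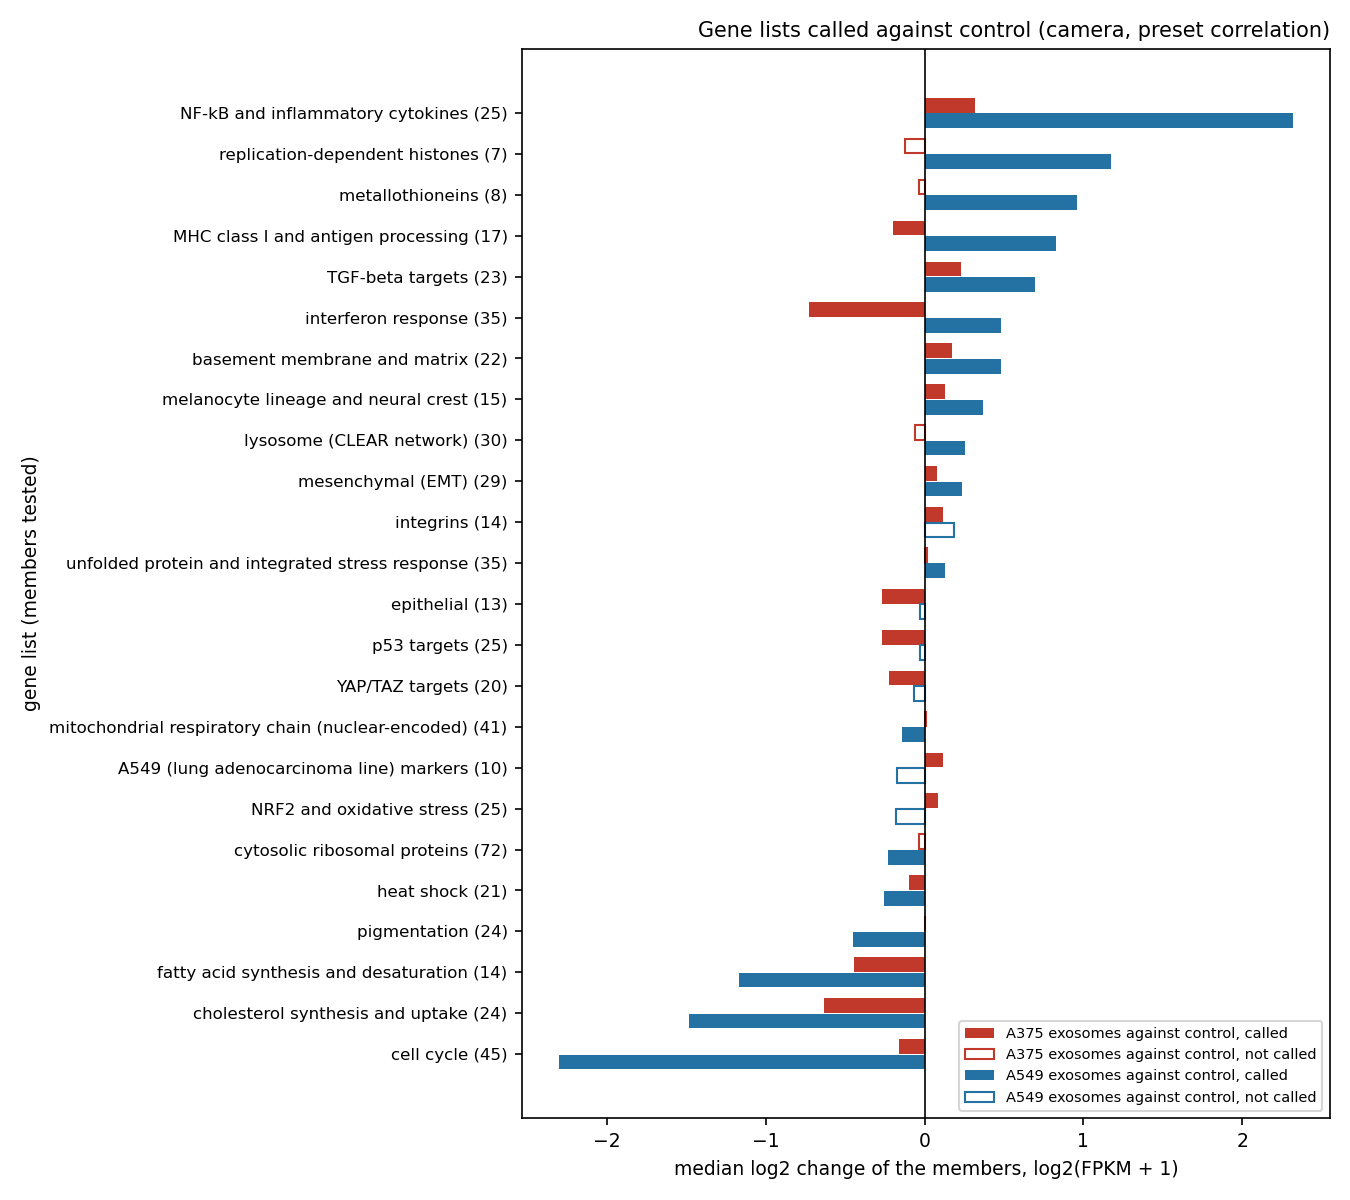
Median log2 change on log2(FPKM + 1) (x axis) of the tested members of each gene list called in at least 1 comparison with control (y axis, members in brackets), after A375 and A549 exosomes; filled bars were called by camera with a preset correlation, open bars were not. The cell cycle median was -0.16 after A375 and -2.30 after A549 exosomes, and the interferon median -0.73 and 0.48.

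Set directly against each other, the A549 group carried more mRNA of inflammatory genes and the A375 group more mRNA of cell cycle genes. CXCL10, a chemokine induced by interferons, was at 6.92 ± 3.18 FPKM after A375 and 374 ± 36.4 after A549 exosomes (SD, n = 3 per group), a log2 difference of -5.66 ± 0.35, adjusted p = 1.1e-05 by limma. FDCSP and CCL20 were also lower after A375 exosomes, with log2 differences of -5.71 ± 0.22 and -5.05 ± 0.10. CDK1 was higher after A375 exosomes by 2.76 ± 0.08, adjusted p = 3.9e-07, and ACAT2 by 1.87 ± 0.05, adjusted p = 3.9e-07. TGFBI differed by 0.02 ± 0.06, adjusted p = 0.86, and IL24 by -0.30 ± 0.13, adjusted p = 0.10.

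Between the exosome groups 6121 genes differed (38.2% of all tested genes), 3296 higher and 2825 lower after A375 exosomes. Of these, 913 differed at least 2-fold, 419 higher and 494 lower. TPM rescaling gave 3722, with 2413 higher and 1309 lower, but without the 8 rows of A549 replicate 2 it gave 2835 higher and 3320 lower, and with no filter 2988 were higher and 3171 lower. Camera called 18 lists, 7 higher and 11 lower after A375 exosomes, and 2 with an estimated correlation. All 45 cell cycle genes were higher, over all genes and adjusted over the list alone (median 2.08, adjusted p = 4.0e-32; adjusted p = 0.029 with an estimated correlation). Of 25 NF-kB genes 24 were lower (median -1.93, adjusted p = 2.2e-19; adjusted p = 0.036 with an estimated correlation), 25 adjusted over the list alone. Of 35 interferon response genes 29 were lower, 32 adjusted over the list alone (median -1.13, adjusted p = 6.7e-10; adjusted p = 0.34 with an estimated correlation). Of 24 pigmentation genes 18 were higher, 18 adjusted over the list alone (median 0.41, adjusted p = 5.6e-08; adjusted p = 0.13 with an estimated correlation). Of 24 cholesterol genes 19 were higher and 1 lower, 21 and 1 adjusted over the list alone (adjusted p = 4.9e-10; adjusted p = 0.13 with an estimated correlation).

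Across genes, the log2 changes after A375 and A549 exosomes correlated at r = 0.389, where genes are not independent replicates. Unchanged groups simulated against the same 3 controls gave 0.503. The covariance was 0.0833 against 0.0350 simulated, a difference of 0.0483. Genes that rose in both numbered 158, against 36.6 for independent lists, and genes that fell in both 152, against 42.4. The simulated count in the same direction was 0.01. Unchanged groups give almost no calls in either comparison, so that count does not measure how far shared controls raise the overlap. Part of the excess may come from the shared controls, since 3 controls cannot be split. The 310 genes called in the same direction became 110, 107 and 127 without control replicates 1, 2 and 3, 110 without A375 replicate 2, and 181, 187 and 184 without A549 replicates 1, 2 and 3. Among the 310, 182 changed by more after A549 exosomes, 16 by more after A375 exosomes, and 112 had no called difference. ID2, CXCL5, FN1 and HMGCS1 were among the genes further from control after A549 exosomes, with log2 differences between the exosome groups of -0.60, -1.74, -0.85 and 1.36.

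**Figure D4:**
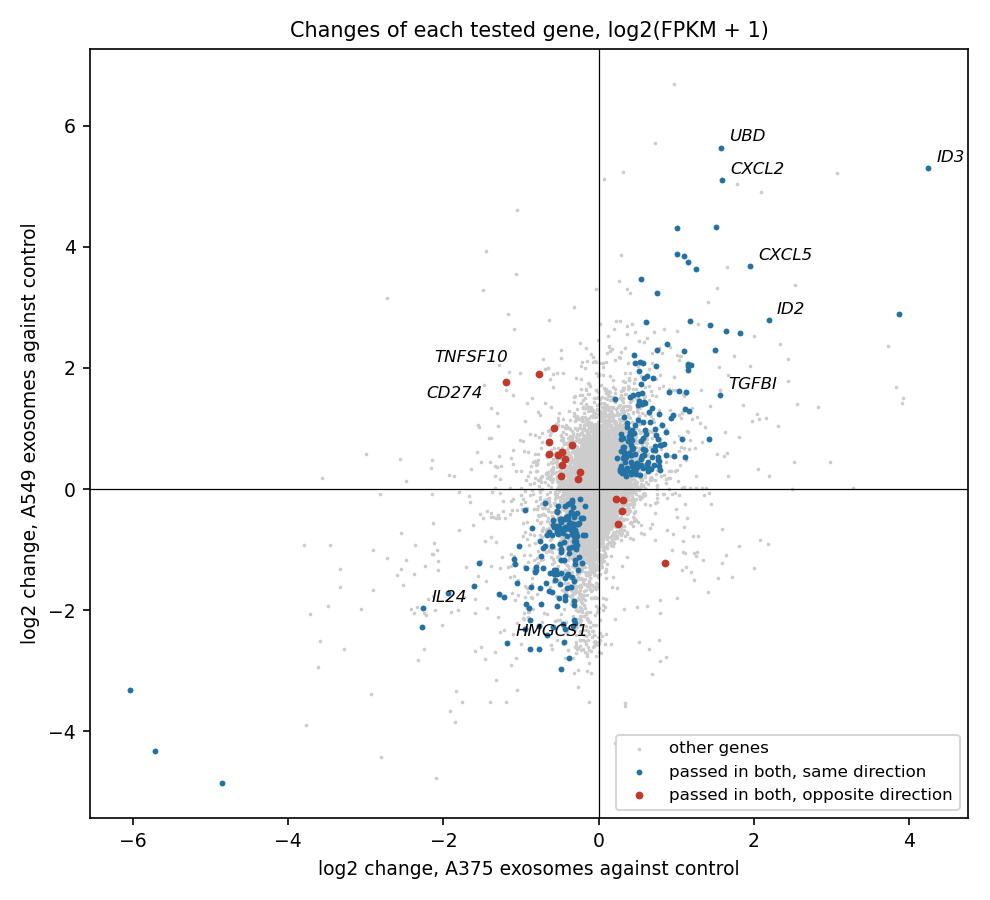
Log2 change on log2(FPKM + 1) of each of 16029 tested genes after A375 exosomes (x axis) and A549 exosomes (y axis), each against control; blue points passed in both comparisons in the same direction (310) and red points in opposite directions (18). ID3 lies at 4.25 and 5.30, and CD274 at -1.20 and 1.77.

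Opposite changes were called for 18 genes, with 79.3 given by independent lists. That count was 6, 2 and 7 without control replicates 1, 2 and 3, 82 and 3 without A375 replicates 1 and 2, and 6, 6 and 7 without A549 replicates 1, 2 and 3. It was 2 under TPM rescaling, 3 in fits of only 2 groups, 9 with no filter, 12 with the replicate block and 73 with the trend on GC content removed. CD274, the gene of the immune checkpoint ligand PD-L1 on chromosome 9, 5450503 to 5470566, plus strand (ENSG00000120217), was at 7.54 ± 1.81 FPKM in control, 2.76 ± 0.955 after A375 and 27.8 ± 1.77 after A549 exosomes (SD, n = 3 per group). Its log2 change was -1.20 ± 0.22, adjusted p = 0.032 after A375 and 1.77 ± 0.22, adjusted p = 0.00038 after A549 exosomes, with a difference of -2.97 ± 0.22, adjusted p = 2.8e-05. The fall after A375 exosomes was not called without control replicate 2 (adjusted p = 0.13), control replicate 3 (0.11), A375 replicate 2 (0.074) or A549 replicates 1 (0.065), 2 (0.061) and 3 (0.066).

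Markers of other cell types were measured in every group. Of 25 markers of the A549 line, 18 were under 3 FPKM in control and 0 of these were above 3 FPKM in either exosome group, with medians of 0.0642 FPKM in control, 0.0476 after A375 and 0.191 after A549 exosomes. Camera called the 10 tested A549-line markers higher after A375 exosomes (median 0.11, adjusted p = 0.013; adjusted p = 0.12 with an estimated correlation), with 0 passing by limma, or 1 up and 0 down adjusted over the list alone, and 2 at unadjusted p under 0.05. That call was lost without A375 replicate 1 (adjusted p = 0.086), the median was 0.02 with no filter, and the list was not called after A549 exosomes (adjusted p = 0.51). Of 21 markers of the A375 line, 19 were under 3 FPKM in control and 0 of these exceeded it in either exosome group. The same held for the 12 endothelial and 16 of 18 leukocyte markers under that level. Of 17 keratinocyte markers under 3 FPKM in control, KRT6B and KRT17 exceeded it after A549 exosomes. KRT6B rose from 0.850 ± 0.0177 to 2.19 ± 0.276 FPKM after A375 exosomes and to 3.37 ± 0.286 after A549 exosomes. Of 14 fibroblast markers under 3 FPKM in control, DCN exceeded it in both exosome groups and CXCL12 after A549 exosomes (log2 3.44 ± 0.12, adjusted p = 4.2e-07).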

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

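The tests of A549-line markers, of interferon genes moving together and of other splits of the libraries and the removal of the trend on GC content were chosen only after the result was seen.

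Many more genes changed after A549 exosomes (6425) than after A375 exosomes (395). If shallower A549 libraries were the whole cause, the gap would sit among low genes. Yet among the 4007 genes with the highest mean FPKM, 2044 changed after A549 and 169 after A375 exosomes, 12.1 times as many. Among lower genes it was 15.1 to 26.6 times as many. The share changed after A549 exosomes was 51.0% among those 4007 genes and 31.9% among the 4008 lowest. After A375 exosomes it was 4.2% and 1.2%. The ratio thus rose while both shares fell, so it does not by itself point to depth. A part played by depth among lower genes was not excluded. RNA or cells of the A549 line carried into the cultures would bring its abundant transcripts, but the 18 A549-line markers under 3 FPKM in control had a median of 0.191 FPKM in the A549 group and 0.0642 in control. The line the exosomes came from stays open as an untested biological explanation. Differences in the amount or the preparation of the vesicles stay open as well, since the labels give 1 optical density for both and do not say how many preparations were made.

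Genes of cholesterol synthesis and uptake were lower after both kinds of exosome (camera adjusted p = 1.2e-32 after A375 and 3.6e-16 after A549 exosomes, and adjusted p = 0.027 and 0.080 with an estimated correlation), and the pattern after A375 exosomes was tested. With the trend on GC content removed from each library, the median log2 change of the list was -0.64, so that trend does not account for it. The median closest to 0 in the 9 fits without 1 library was -0.61, without A375 replicate 2, so no single library carries that median. The members called lower were 12 in that fit and without control replicate 2, in place of 21, and 5 under TPM rescaling. They were 20 under TPM rescaling without the 8 rows of A549 replicate 2. A response to the vesicles may explain the pattern, as may lipid or medium carried with the pellets, and neither was tested, since no vehicle arm was analysed here.

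Interferon response genes had a median log2 change of -0.73 after A375 exosomes with 35 of 35 members below 0, but limma called 0 of them, with 21 at an unadjusted p under 0.05, and camera with an estimated correlation did not call the list (adjusted p = 0.321). The trend on GC content does not account for that median, which was -0.71 with the trend removed. Without A375 replicate 2 the median was -0.37, which lies between the values set in advance for and against a pattern of that library alone, so a shift of that library and a shift of the group cannot be told apart with 3 libraries. Members of the list may rise and fall together between libraries of 1 group. The loss of the camera call at adjusted p = 0.321 with an estimated correlation would follow from that. Yet it is not particular to this list, since 2 of the 17 lists called after A375 exosomes were still called in that setting.

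Changes in opposite directions from control were found for 18 genes. That count ranged from 2 (without control replicate 2) to 82 (without A375 replicate 1) in the fits without 1 library. Under each setting, the difference between the exosome groups was called for all genes counted as opposite in that setting. These were not always the same genes, and under TPM rescaling 2 of the 18 were among them. That difference spans both changes from control, so it adds no separate evidence. After CD274 the largest differences, chosen after their values were seen, were those of TNFSF10 (log2 change -0.77 after A375 and 1.90 after A549 exosomes) and TMIGD3 (0.86 and -1.21). CD274 had a log2 difference between the groups of -2.97 (adjusted p = 2.8e-05 by limma). In A549 replicate 2 alone, 8 rows on chromosome 1, from position 629062 to 634922, summed to 251251 FPKM and were listed at 0 in the other 8 libraries.

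Each pair of groups gives 10 splits of its 6 libraries, too few for a share under 0.05, and in each of the 9 counts 1 split, the real one, reached the real value. For A375 exosomes against control the real values and the highest of the other splits were 395 and 9 genes, 51 and 9 genes at least 2-fold, and 17 and 12 lists. For A549 exosomes against control they were 6425 and 6 genes, 1060 and 6 genes at least 2-fold, and 18 and 15 lists. Between the exosome groups they were 6121 and 7 genes, 913 and 7 genes at least 2-fold, and 18 and 11 lists. Every other split mixes libraries of both groups, so a difference between the groups enters the spread and lowers its gene counts. Those gene counts therefore do not measure what unchanged groups would give. Up to 12, 15 and 11 lists were called in other splits. Those splits can still hold part of the difference between the groups. Their list counts therefore do not measure what unchanged groups would give either.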

How the results depend on the processing

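The removal of the trend on GC content, A549 replicate 1 alone, TPM rescaling without 8 rows and protein-coding genes only were tests chosen only after the result was seen.

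Results for single named genes were counted under each setting as the same, weaker, stronger or reversed. The same covers genes called in 1 direction both times and genes called neither time, so it is not a count of kept calls. For A375 exosomes against control 1674 cases were the same, 365 weaker and 31 stronger. For A549 exosomes against control 2987 were the same, 47 weaker and 3 stronger. Between the exosome groups 3063 were the same, 58 weaker and 11 stronger. Of the 66 named genes called after A375 exosomes, 16 kept their call under all settings. PMEL reversed under quantile normalization, from -0.17 to 0.22 ± 0.09 (adjusted p = 0.098) after A549 exosomes and from 0.13 to -0.11 ± 0.09 (adjusted p = 0.39) between the exosome groups; the cause was not tested. Genes changed by A375 exosomes numbered 395, against 251 with no filter, 52 under TPM rescaling, 110 with only the 2 groups compared and 871 with the trend on GC content removed. Genes changed in the same direction by both numbered 310, against 183 with no filter, 45 under TPM rescaling and 636 with the trend on GC content removed. TPM rescaling gave 4062 genes for A549 exosomes against control and 3722 between the exosome groups, and A549 replicate 1 alone, assumed to vary like the libraries of the other groups, gave 2655. TPM rescaling without the 8 rows gave 357 and 6569 genes for A375 and A549 exosomes against control, so those rows account for the losses against control under TPM. With no filter 36888 rows were tested, and fewer libraries entered the fits of 2 groups and of replicate 1 alone; for the GC setting the cause was not tested. With an estimated correlation camera called 2, 3 and 2 lists in place of 17, 18 and 18; the cause was not tested.

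Without 1 library in turn, genes changed ranged from 133 to 517 (A375 exosomes against control), 4955 to 7075 (A549 exosomes against control) and 4572 to 6954 (between the exosome groups), and genes changed at least 2-fold from 27 to 69, 966 to 1092 and 822 to 1085. Lists called ranged from 14 to 17, 17 to 20 and 18 to 19, genes changed in the same direction by both from 107 to 330, and the correlation from 0.293 to 0.441. The lowest of these for A375 exosomes were 133 genes without A375 replicate 2 and 27 without control replicate 1, and 107 in the same direction without control replicate 2. Fewer libraries widen the standard error or leave fewer degrees of freedom by construction.

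With the replicate number as a replicate block, 284 and 6693 genes changed after A375 and A549 exosomes against control and 6495 differed between them, with 49, 1066 and 921 at least 2-fold, 17, 18 and 18 lists, and 228 genes in the same direction. The labels do not say that a number pairs libraries. Deviations from the group means correlated at -0.04 to 0.23 in the 9 pairs with the same number, 2 of them over 0.1, and at -0.24 to 0.07 in the 18 other pairs, and 7 of 9 libraries matched their own number best, which is a hint from the data and not from the design. Depth is known only in relative terms, and in simulated data 35.8% of log2 changes of 0.5 were recovered, so small changes after A375 exosomes can be missed.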

Other observations

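The lists of interferon-gamma type, complement and recombination genes and the comparison of replicates by GC content were tests chosen only after the result was seen, as was the criterion for the BMP-SMAD targets, which were themselves listed before their test, once the changes of the ID genes were known.

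After A549 exosomes, all 24 tested genes of an added list of interferon-gamma type and MHC class II genes rose against control (camera median 1.43, p = 1.1e-15, and p = 0.035 with an estimated correlation). IDO1, which breaks down tryptophan, was at 8.80 ± 2.32 FPKM in control, 3.47 ± 1.40 after A375 and 70.1 ± 1.43 after A549 exosomes (SD, n = 3 per group). HLA-DRA, an MHC class II chain, was at 162 ± 18.4, 147 ± 6.54 and 394.6 ± 13.7 FPKM, and CIITA, the transactivator of that class, rose by 1.33 ± 0.12 on the log2 scale after A549 exosomes. After A375 exosomes 3 of the 24 fell and none rose by limma, with an unadjusted p under 0.05 for 10 (camera median -0.24, p = 1.2e-06, and p = 0.15 with an estimated correlation). Of 12 complement and acute phase genes 10 rose after A549 exosomes (median 2.22, p = 1.6e-07, and p = 0.047 with an estimated correlation). C1S, a protease of the classical complement pathway, was at 86.2 ± 14.4 FPKM in control, 94.8 ± 17.5 after A375 and 438.6 ± 16.0 after A549 exosomes. The pentraxin gene PTX3 rose after both, by 0.76 ± 0.10 and 3.23 ± 0.10 on the log2 scale.

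Of 23 genes of homologous recombination and the Fanconi anaemia pathway, 21 fell after A549 exosomes (median -1.65, p = 2.3e-14, and p = 0.00077 with an estimated correlation). FANCI, a target of the Fanconi core complex, was at 107 ± 7.79 FPKM in control, 93.7 ± 12.5 after A375 and 16.4 ± 1.07 after A549 exosomes. After A375 exosomes limma called none of the 23 and gave 11 an unadjusted p under 0.05, while the list lay lower by camera (median -0.24, p = 1.2e-07, and p = 0.0049 with an estimated correlation).

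A hypothesis on the ID genes was tested. ID1, ID2 and ID3 rose in both exosome groups, with log2 changes of 1.49, 2.19 and 4.25 after A375 and 2.30, 2.79 and 5.30 after A549 exosomes, and BMP-SMAD signalling is a candidate explanation. Of 7 other tested BMP-SMAD targets, limma called none after A375 exosomes and gave 5 an unadjusted p under 0.05, with a median log2 change of 0.39 (camera p = 6.9e-05, and p = 0.020 with an estimated correlation). After A549 exosomes ATOH8 rose by 0.94 ± 0.18 and DLX2 by 0.89 ± 0.11 while ID4 fell by 0.37 ± 0.09 on the log2 scale, with a camera p of limma of 0.30. BMP-SMAD signalling and another inducer of the ID genes cannot be told apart here, because 7 targets were above the filter and they moved both ways after A549 exosomes.

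Replicates 1 and 3 of the control and A375 groups differed by GC content. The deviation of a library from its group mean was correlated with GC content across 6860 genes, a part of the 15779 tested genes with a GC value. The correlation was 0.56, 0.01 and -0.57 in control replicates 1, 2 and 3. It was 0.64, 0.02 and -0.66 in A375 replicates 1, 2 and 3, and 0.19, -0.14 and -0.03 in A549 replicates 1, 2 and 3. The log2 changes correlated with GC content at -0.18 for A375 and 0.14 for A549 exosomes against control.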
